A study of Mus musculus with 574 samples.

How the data were processed

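The samples were single cells from cultures of neonatal mouse cardiac fibroblasts (outbred CD1 strain) purified for the surface protein Thy1. Cells under reprogramming received separate retroviruses for the transcription factors Mef2c, Gata4 and Tbx5. Per the labels' protocols, control cells were left untransduced or received retroviruses for DsRed, a red fluorescent protein, and for puromycin resistance. On day 3 live cells were sorted and captured on C1 microfluidic chips, and poly-A RNA was turned into libraries with the SMARTer and Nextera XT kits, which do not mark the strand. Reads of overlapping genes on the same or the opposite strand therefore cannot be told apart.

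The labels describe 7 separate capture experiments, named plates here. There were 2 control plates, 3 reprogramming plates and 2 mixed plates, the last holding reprogramming cells and retroviral control cells loaded together in about equal parts. The labels do not say which control plate was left uninfected, so the control plates were kept as one group. The plate was taken as the replicate, since cells of one plate are not replicates. The p-values thus measure the spread between capture experiments, and nothing in the labels says whether these came from separate litters. If the control plates differed in infection, the spread between them also holds any effect of it. The difference between reprogramming and control plates may then hold such an effect too.

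Raw counts per gene were deposited for 513 cells of the 574 samples in the labels. Per the submitters' processing notes, FastQC, TopHat2 2.1.0, HTSeq 0.6.1p1 and DESeq were used with mouse build mm10. The counting mode and the strand setting were not given in the sources used here. The authors also deposited a normalized signal, which per the labels' design text used spike-in RNA for a technical size factor. In that signal each cell was checked to be the raw counts times one constant (0 of 4201866 nonzero values were off by over 1%). A further deposited signal, corrected with ComBat per the sheet name, covered 454 cells the authors kept as non-immune and 14414 rows. A last deposited sheet gave a class name for 454 cells, of which 452 could be matched to a sample. How the classes were made was not given in the sources used here, and their abbreviations are used as written.

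Of the 23423 count rows, 27 had gene symbols turned into dates (0.840% of reads) and 3 were the constructs DsRed, GFP and Puro (0.107% of reads). Both kinds were left out of library sizes and tests, which left 23393 genes. There were no spike-in rows in the counts used here, so RNA content per cell was not computed. The tables held 8 blank columns, which were not used. No 2 cells had identical counts, and the highest correlation of log2 values between any pair of cells was 0.982. Each cell held 358280 to 2700137 reads on genes (median 1229557). Intervals and floors cover counting error only, because the reads carry no molecular identifiers.

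Choices named in the next sentences were made before the data were examined, unless stated otherwise. Counts of non-immune cells were summed per plate and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. All 7 plates entered one fit with 3 groups. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. Values per plate are TMM-scaled CPM, counts divided by the plate's scaled library total. For a gene with 0 reads in a group, the fold was computed against a floor of 3 counts over the group. For a gene with 1 to 3 reads, the ratio is given with its exact 95% interval.

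Fixed lists (21) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with fry for direction, and adjusted over the 21 lists. Per-gene calls were also adjusted over the list alone. Named genes were the 3 factors, and the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between the plates of the groups compared. For the other contrasts 5 of each were taken. Up to 4 genes with the smallest p were added from each list. Klhl4 and the class genes said to be so were chosen after their values were seen. GENCODE coordinates of the matching build (GRCm38) were found for 249 of 251 named genes. Exons of another annotated gene overlapped 74 of them.

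The authors' classes were compared within plates on sums of at least 5 cells per plate and class, with the plate as a block. If the classes were made from these expression values, p-values between them are too small, so the counts are given as descriptions. The design had set a comparison of reprogramming with control plates inside one class. No class occurred both in control plates and in other plates, so CCIiFib cells were compared with CCIFib cells instead, a choice made after seeing the classes. Shares of cells with all 3 factors were taken after thinning each cell to 50000 reads, which left no cell out. Shares and rank correlations per plate were compared by exact two-sided permutation tests of plate values. With 3 against 2 plates there are 10 arrangements and the smallest p is 0.1. Cell-level correlations were taken after removing log depth, one value per plate.

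Tests on simulated counts with 200 changed genes gave the following. Over 15270 genes of the comparison of reprogramming with control plates, 0% of genes changed by 1 log2 unit were recovered, 36% at 2 units, 60% at 3 and 66% at 4. Among genes of at least 10 CPM these shares were 0%, 77.3%, 93.3% and 96.4%. Of 90 calls, 9 were false. For CCIiCM against CCIiFib (14850 genes) the shares were 8%, 26%, 48% and 58%, with 0 false among 70 calls. Alternatives were other size factors, DESeq2 1.42.0, other low-count filters, other sets of cells, the authors' normalized values, equal weight per cell, each plate left out, 2 groups only and a replicate block. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.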

Results

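Messenger RNA was measured in single cells of neonatal mouse cardiac fibroblast cultures on day 3 after transduction with Mef2c, Gata4 and Tbx5, a set of cardiac transcription factors used to turn fibroblasts into cardiomyocyte-like cells. The counts held 77 and 82 cells of control plates 1 and 2, 69, 85 and 81 cells of reprogramming plates 1, 2 and 3, and 68 and 51 cells of mixed plates 4 and 5. The authors kept 73, 73, 67, 73, 56, 67 and 45 of these as non-immune. Median reads per cell were 1.38e+06, 1.122e+06, 1.185e+06, 1.323e+06, 1.127e+06, 1.188e+06 and 2.117e+06 in the same order, over 513 cells. Mixed plate 5 thus had the highest median depth per cell and the fewest cells.

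The first question was whether the delivered factors were present in the plates labelled as reprogramming. Gata4 rose from 48.2 ± 4.64 CPM in control plates (SD, n = 2) to 583 ± 61.6 CPM in reprogramming plates (SD, n = 3), Tbx5 from 3.81 ± 3.33 to 593 ± 234 CPM, and Mef2c from 51.1 ± 26.4 to 692 ± 258 CPM. The log2 fold changes were 3.60 ± 0.34 (SE) for Gata4, 7.29 ± 0.84 for Tbx5 and 3.76 ± 0.50 for Mef2c, with adjusted p of 0.00980, 0.0158 and 0.0266 by the edgeR quasi-likelihood test. Mixed plates held 347 ± 159 CPM of Gata4, 220.3 ± 107 CPM of Tbx5 and 493 ± 152 CPM of Mef2c (SD, n = 2). The genes lie on chromosome 14 (63198922 to 63271692, Gata4), chromosome 5 (119832668 to 119885219, Tbx5) and chromosome 13 (83504034 to 83667080, Mef2c) of GRCm38. Reads of viral and endogenous transcripts were not separated. Without control plate 1, 0 of the 3 factors passed the threshold, and without control plate 2, 1 did.

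**Figure D1:**
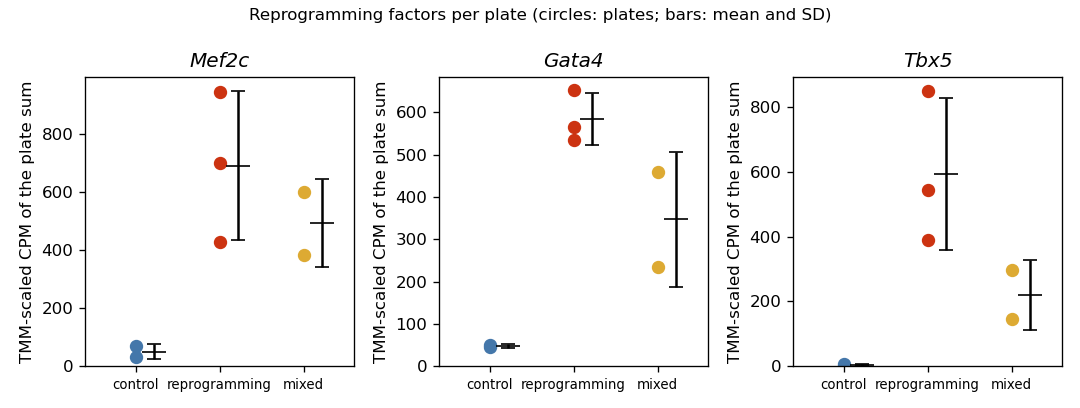
Plate values of Mef2c, Gata4 and Tbx5 (TMM-scaled CPM of the summed counts, vertical axis from 0) for control, reprogramming and mixed plates, with circles for plates and bars for the mean and SD of each group. All 3 reprogramming plates lie above both control plates for each factor, for example 583 against 48.2 CPM on average for Gata4.

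Cells carrying reads of Mef2c, Gata4 and Tbx5 together made up 64.2%, 94.5% and 89.3% of reprogramming plates 1, 2 and 3 at 50000 reads per cell, a mean of 82.7% ± 16.2 (SD, n = 3). In control plates the share was 0.685% ± 0.969 (SD, n = 2), and in mixed plates 4 and 5 it was 59.7% and 44.4%. The exact two-sided permutation test gave p = 0.1, the smallest that 10 arrangements allow. Without thinning, 100% of cells in reprogramming plates and 30.1% ± 3.88 in control plates (SD, n = 2) had a read of each factor (exact permutation p = 0.1). The unthinned share was 98.5% and 97.8% in mixed plates 4 and 5, although these plates also held retroviral control cells. A read of each factor without thinning thus does not by itself mark delivery of all 3.

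Reprogramming and control plates were then compared across 15613 genes. Sarcomere genes were among the named rises. Ttn, the giant elastic protein of the sarcomere, went from 1.11 ± 0.613 CPM in control plates to 979.5 ± 919 CPM in reprogramming plates (log2 fold change 9.80 ± 1.19, adjusted p 0.0182). Actc1 (cardiac actin) and Tnni3 (cardiac troponin I) rose by 10.30 ± 1.60 and 10.34 ± 1.34 log2 units, and Csrp3 and Smpx, both muscle proteins, by 10.71 ± 1.41 and 8.88 ± 0.86. Among falls were Lox, which crosslinks collagen (589 ± 104 to 93.3 ± 30.3 CPM, log2 fold change -2.66 ± 0.32), and the cytokine Il6 (91.2 ± 33.7 to 15.1 ± 3.66 CPM, log2 fold change -2.60 ± 0.31). In all, 97 genes passed the threshold by edgeR, 65 higher and 32 lower in reprogramming plates, and 2222 had an unadjusted p under 0.05.

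The other named rises were Synpo2l (7.85 ± 0.89 log2 units), Ppp1r3c (7.48 ± 1.08), Ncf4 (8.44 ± 1.35), Pvalb and Pga5. Pvalb, a calcium-binding protein of fast muscle and of some neurons, had 1 read in control plates and 8852 in reprogramming plates, a ratio of 5796 (95% interval 1040 to 229000). Pga5, a pepsinogen gene, had 0 reads in control and mixed plates and 7451 in reprogramming plates, at least 1626-fold higher against a floor of 3 counts over the control group. A single cell held 99.5%, 80.9% and 99.6% of the Pga5 reads of reprogramming plates 1, 2 and 3, and 11, 7 and 6 cells had any read. Falls also included Wisp2 (474 ± 78.2 to 78.4 ± 10.2 CPM), Ctla2a (543 ± 103 to 36.2 ± 25.5 CPM), Mfap4 (172 ± 12.1 to 22.4 ± 12.1 CPM), Igfbp3 (50.6 ± 26.5 to 5.68 ± 1.48 CPM), Slc4a4 (58.4 ± 23.0 to 10.3 ± 1.04 CPM) and Phyhd1 (53.7 ± 6.06 to 10.1 ± 4.47 CPM). Bst1 and Sfrp2, a secreted regulator of Wnt signalling, fell by 8.55 and 8.38 on the log2 scale. Sfrp2 was uneven in control plates, at 34.9 ± 39.4 CPM. Exons of Ttn, Tnni3, Lox, Bst1, Sfrp2, Ctla2a, Mfap4 and Phyhd1 overlap those of another annotated gene, so their reads are not wholly assignable.

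Read by list, the sarcomere and contractile list was higher as a whole (camera adjusted p 1.21e-16; adjusted p = 0.277 with an estimated correlation). Of its 26 measured members 9 rose and 0 fell, or 19 up and 1 down adjusted over the list alone, with a list median log2 fold change of 4.86, also with its 3 members at 0 control reads set to their bound. That median was 3.62 without reprogramming plate 2, 3.20 with equal weight per cell, 2.91 with the authors' ComBat values and 2.38 with their normalized values. Des rose from 12.9 ± 1.20 to 160.1 ± 36.9 CPM and Mybpc3 from 2.02 ± 0.490 to 56.3 ± 19.2 CPM. Of 17 calcium handling genes 1 rose, Sln, an inhibitor of the sarcoplasmic calcium pump (7.31 ± 1.09 log2 units), and 6 did adjusted over the list alone (list adjusted p 0.00156, and 0.419 with an estimated correlation). Casq2 stood at 14.1 ± 5.60 and 127 ± 60.1 CPM without passing (adjusted p 0.0563). The factor list itself had 3 of 3 up (list adjusted p 4.26e-06, and 0.241 with an estimated correlation). The fatty acid oxidation list was higher (adjusted p 0.00337, and 0.277 with an estimated correlation), with 0 of 15 passing and 2 adjusted over the list alone. Its member Acaa2 stood at 73.3 ± 33.6 and 781 ± 429 CPM (adjusted p 0.0563).

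The fibroblast and extracellular matrix list was lower (camera adjusted p 1.45e-08, and adjusted p = 0.277 with an estimated correlation). Of 34 members 2 fell, Lox and the proteoglycan Bgn (5286 ± 340.2 to 1970 ± 43.6 CPM), and 14 fell adjusted over the list alone. Fstl1 had a log2 fold change of -1.35 ± 0.23 and Col3a1 of -1.97 ± 0.34, with adjusted p of 0.0541 and 0.0551. Lower lists also included smooth muscle genes (adjusted p 0.0123, 0 of 12 passing, 2 adjusted over the list alone), interferon response (0.0205, 1 of 18 down, Ifit3), inflammatory cytokines and chemokines (0.0205, 1 of 18 down, Il6; the list median of -0.79 was 0.079 without control plate 2) and unfolded protein response (0.00388, 0 of 15 passing, 3 adjusted over the list alone). With an estimated correlation the adjusted p was 0.577 for smooth muscle and for cytokines, 0.602 for interferon response and 0.419 for unfolded protein response. Mitosis genes were lower as a list (0.00366, and 0.577 with an estimated correlation, 0 of 25 passing), and adjusted over the list alone 1 rose and 3 fell. Lists with adjusted p above 0.05 were cardiac regulators (0.644), TGF-beta targets (0.126), DNA replication (0.114), immune markers (0.644), splicing regulators (0.794), immediate early genes (0.263), glycolysis (0.323), oxidative phosphorylation (0.0568) and skeletal muscle (0.654). For the immune list the median log2 fold change was positive (0.89) while camera ranked it as lower. That median was -2.51 without reprogramming plate 3, and -0.39 with the authors' normalized values.

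Markers of other cell types moved with the groups. The endothelial list was lower in reprogramming plates (adjusted p 0.00156, 0 of 11 passing, 3 down adjusted over the list alone, median log2 fold change -2.32), as was the epicardial list (0.0205, 0 of 13 passing, 3 down adjusted over the list alone). With an estimated correlation the adjusted p was 0.511 and 0.55. The endothelial median was -0.72 without control plate 1, -4.07 without reprogramming plate 1 and -3.49 without either mixed plate in turn. It was -0.22 without the cells holding at least 4 endothelial markers. Emcn, an endothelial gene, stood at 248 ± 161 and 4.15 ± 6.92 CPM, and Gpm6a, from the epicardial list, at 98.3 ± 88.4 and 2.86 ± 1.92 CPM. Non-immune cells with at least 4 endothelial markers at 10 CPM numbered 6 and 2 in control plates and 3, 0 and 0 in reprogramming plates. Those with at least 6 epicardial markers numbered 11 and 7 against 4, 3 and 1. Without both kinds of cells, a setting added after seeing the data, 135 genes passed, 80 of them among the 97. The medians of the epicardial and mitosis lists turned positive there (0.26 and 0.11), as they did with only the CCI classes (0.079 and 1.33). Cells were removed by markers of the endothelial and epicardial lists themselves. The shifts of those list medians after removal thus follow at least in part from the selection.

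No list passed camera with an estimated correlation. By fry the factor (adjusted p 0.00368), sarcomere (0.0138) and fatty acid oxidation lists (0.0386) passed, all higher. The fibroblast list had an adjusted p of 0.0540 by fry, and no other list was lower than that. With either control plate left out, the fit held 1 control plate and few if any of the 97 still passed. The count of 97 fell to 20 without reprogramming plate 2 and to 55 without reprogramming plate 3 (19 and 44 of them among the 97), while DESeq2 gave 1059. The authors' normalized values moved the median gene by -0.37 log2 units and gave 140 higher and 1396 lower genes. All 97 kept their direction in each setting that measured them, and the fatty acid oxidation median turned negative (-0.056) with the authors' values unless set against the median gene.

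**Figure D2:**
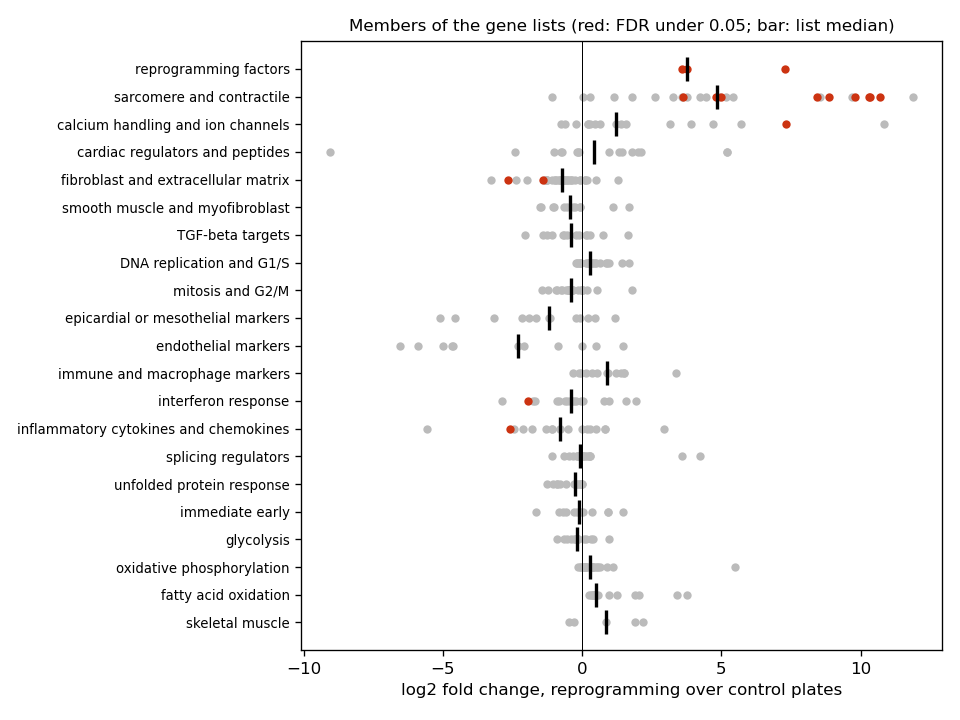
Log2 fold change of reprogramming over control plates (horizontal axis) for each measured member of the 21 fixed lists, red where the adjusted p was under 0.05, with a bar at each list's median. The sarcomere list has 9 red members and a median of 4.86 (2.38 with the authors' normalized values), and fitted values of genes with 0 control reads depend on a prior count.

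Mixed plates, in which about equal parts of reprogramming and retroviral control cells shared a chip, were compared with control plates. The factors stood higher by 2.85 ± 0.34 (Gata4), 5.86 ± 0.80 (Tbx5) and 3.27 ± 0.50 (Mef2c) log2 units, with adjusted p of 0.112, 0.147 and 0.152 by edgeR. No gene of 15613 passed, while 1038 had an unadjusted p under 0.05 and DESeq2 called 217. The factor and sarcomere lists were higher (camera adjusted p 3.57e-07 and 2.38e-13, and 0.17 and 0.408 with an estimated correlation), with 3 of 3 and 13 of 26 members up adjusted over the list alone. The epicardial list was lower (adjusted p 0.00563, 11 of 13 members negative, median log2 fold change -1.16), as was smooth muscle (0.00589), and DNA replication (0.0249) and oxidative phosphorylation (0.0383) were higher. With an estimated correlation the adjusted p was 0.718 for each of them. Smpx stood at 44.5 ± 15.9 CPM and Ttn at 259.9 ± 166 CPM in mixed plates. Il6 (81.2 ± 5.20 CPM) and Ctla2a (705 ± 233 CPM) were near the control level there. Of the 97 genes called between reprogramming and control plates, 92 (94.8%) had the same sign in mixed plates and 91 lay between the means of the other groups, at a median of 36.4% of the way from control. With mixed plates simulated as unchanged from control, which keeps the shared controls, the same sign was found for 65.0% of a mean of 1030 simulated calls, and for 57.0% of the 97 simulated genes with the smallest p. The covariance of the fold changes over all genes was 1.82, against 0.695 simulated. The control plates could not be split, so part of the excess may come from them. The simulation called a mean of 1030 genes where the data called 97. Its changes or its spread between plates thus differ from the data, and the size of the excess is uncertain.

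Between reprogramming and mixed plates 2 genes passed by edgeR, and 1486 had an unadjusted p under 0.05. One was Pga5, at 27.9 ± 4.75 CPM against 0 reads in mixed plates. The other, named after its value was seen, was Klhl4, with 1 read in reprogramming plates and 7.67 ± 1.34 CPM in mixed plates, where a single cell held 100% and 68.9% of its reads. Inflammatory cytokines and chemokines were lower as a list (camera adjusted p 0.00107), with 7 of 18 members down adjusted over the list alone. The sarcomere list was higher (adjusted p 7.43e-05, 4 of 26 up adjusted over the list alone) and the fibroblast list lower (adjusted p 1.02e-06, 4 of 34 down adjusted over the list alone). With an estimated correlation the adjusted p was 0.43 for each of these lists. The endothelial (adjusted p 0.000713, median log2 fold change -1.72), mitosis (0.000176, 23 of 25 members negative) and interferon lists (0.00704) were lower too, with adjusted p of 0.43, 0.43 and 0.47 at an estimated correlation. Smaller list values were 0.0319 for glycolysis (lower), 0.04 for unfolded protein response (lower) and 0.04 for calcium handling (higher), and 0.43, 0.43 and 0.446 with an estimated correlation. Il6 had a log2 fold change of -2.43 ± 0.31 in reprogramming over mixed plates (adjusted p 0.113). No call was left without reprogramming plate 3 or without mixed plate 5, and DESeq2 called 345.

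The authors' classes divided the plates by group. Control plates held the classes CCIFib (80.6% ± 1.58, SD, n = 2) and CCAFib (19.4% ± 1.58). Reprogramming plates held CCIiCM (42.4% ± 11.8, SD, n = 3), CCIiFib (31.3%, 20.5% and 30.4%), CCIpiCM (20.9%, 15.1% and 17.9%), CCAiFib (7.40% ± 6.78) and CCAiCM (4.84% ± 3.77). In mixed plates 4 and 5 the CCIiFib share was 46.3% and 51.1% and the CCIiCM share 19.4% and 15.6%. The 95% exact binomial intervals of the CCIiCM share ran from 20.6% to 43.8%, 42.7% to 66.5% and 28.1% to 55.0% in reprogramming plates 1, 2 and 3. Exact permutation p-values between reprogramming and control plates were 0.1 or 0.2 (adjusted 0.14 to 0.2 over 7 classes). CCIFib and CCAFib occurred in no mixed plate, although these plates were loaded with control cells too. If the class names were given by plate, which is not stated in the sources used here, the shares of 0 and these p-values were fixed by the naming.

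**Figure D3:**
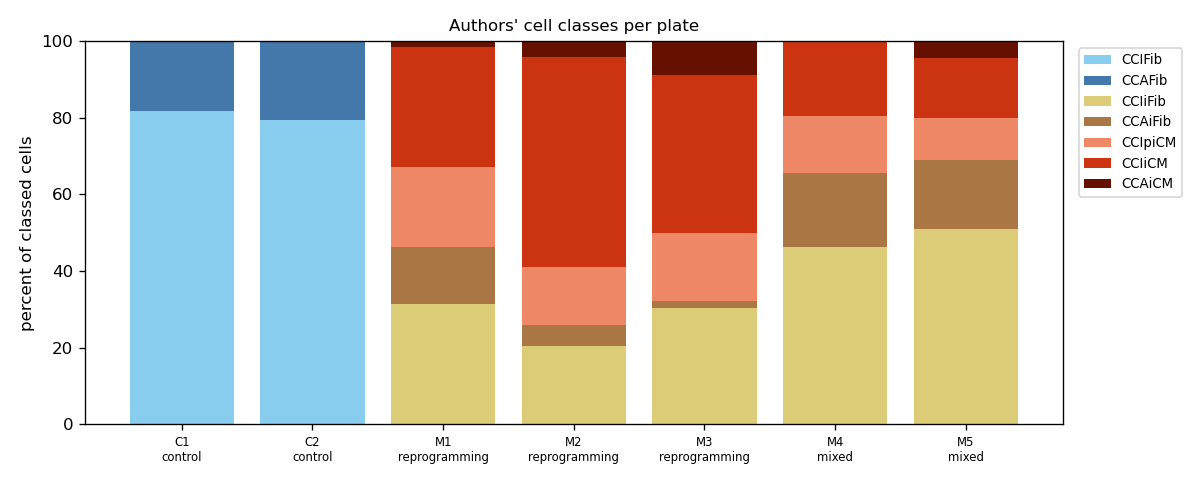
Share of classed non-immune cells (percent, vertical axis) in each of the authors' 7 classes, one stacked bar per plate (C1 and C2 control, M1 to M3 reprogramming, M4 and M5 mixed). Control plates hold only CCIFib and CCAFib, and the CCIiCM share is 31.3%, 54.8% and 41.1% in reprogramming plates 1, 2 and 3 against 19.4% and 15.6% in mixed plates.

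Within plates, CCIiCM cells differed from CCIiFib cells of the same plates in cardiac, matrix and metabolic genes. Myl7, an atrial myosin light chain, stood at 2033 ± 655 CPM in CCIiCM and 30.6 ± 30.7 CPM in CCIiFib (SD, n = 5 plates; log2 fold change 7.16 ± 0.95), Ryr2, the calcium release channel, at 148 ± 84.4 CPM in CCIiCM (log2 fold change 4.57 ± 0.62), and the peptide hormone gene Nppa at 152 ± 163 and 0.590 ± 0.375 CPM. Tcf21, a fibroblast transcription factor, stood at 9.79 ± 5.95 and 192 ± 41.3 CPM, and Fbn1, a microfibril protein, at 84.3 ± 29.0 and 634 ± 116 CPM. The factors differed too, with Mef2c at 1174 ± 205 and 211 ± 122 CPM, Gata4 at 889 ± 291 and 198 ± 89.4 CPM, and Tbx5 at 777 ± 249.9 and 129 ± 99.9 CPM. In all 999 of 15157 genes passed by edgeR with the plate as a block, 429 higher and 570 lower in CCIiCM. CCIiFib cells of mixed plates 4 and 5 held 3111 and 3678 CPM of DsRed on average, against 0 in reprogramming plates. All 3 factors were found in 38.7% and 21.7% of them, against 33.3%, 80% and 70.6% in reprogramming plates 1, 2 and 3. Values over 5 plates may thus partly set reprogramming cells against retroviral control cells.

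By list, CCIiCM cells had 15 of 26 sarcomere genes, 7 of 18 calcium handling genes, 13 of 21 oxidative phosphorylation genes and 4 of 15 fatty acid oxidation genes higher, and 0 lower. Acaa2 stood at 1414 ± 601 and 112 ± 18.1 CPM and Cox6a1 at 1657 ± 429 and 966 ± 359 CPM in CCIiCM and CCIiFib. Lower in CCIiCM were 27 of 34 fibroblast and matrix genes, 5 of 12 smooth muscle genes, 6 of 18 cytokine genes and 8 of 15 unfolded protein response genes, with 0 higher. Asns, asparagine synthetase, stood at 107 ± 28.8 and 516 ± 136 CPM and Tnfaip3, an inhibitor of NF-kB signalling, at 0.817 ± 0.506 and 24.2 ± 18.3 CPM. These lists passed camera with the preset and with the estimated correlation (adjusted p 0.000328 for sarcomere, 0.0122 for calcium handling, 0.0378 for oxidative phosphorylation, 0.0174 for fatty acid oxidation, 0.00257 for fibroblast and unfolded protein response, 0.0334 for smooth muscle and 0.00554 for cytokines, all estimated). If the classes were made from these expression values, these p-values are too small and the lists only describe the classes. The endothelial markers had a median log2 fold change of -2.61 in CCIiCM over CCIiFib, with 7 of 11 members negative, and the list did not pass (adjusted p 0.171, and 0.597 with an estimated correlation). Its member Eng fell (42.4 ± 16.1 against 104 ± 46.8 CPM, adjusted p 0.0201), while Emcn stood at 0.653 ± 1.14 and 56.5 ± 72.0 CPM (adjusted p 0.136) and Esam at 0.253 ± 0.544 and 13.1 ± 18.4 CPM (adjusted p 0.253). With reprogramming plates alone, added after seeing the data, 310 genes passed, Mef2c and Gata4 among them, and Tbx5 had an adjusted p of 0.0501. Left-out plates gave 563 (reprogramming plate 2), 584 (reprogramming plate 3) and 507 (mixed plate 4).

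CCIpiCM cells were set against both other classes. Over CCIiFib, 10 genes passed, 8 higher and 2 lower, with the same limit from the CCIiFib cells of mixed plates. Those outside the naming rule, here Medag and Svep1, were chosen after their values were seen. Smpx (80.4 ± 57.5 against 0.898 ± 0.940 CPM), Ryr2 (95.5 ± 44.9 CPM, log2 fold change 4.05 ± 0.61), Acaa2 (456 ± 226 against 112 ± 18.1 CPM) and Fabp3, a fatty acid carrier (118 ± 79.8 against 26.3 ± 17.9 CPM), were higher (SD, n = 5 plates), and Medag and Svep1 were lower by log2 fold changes of -3.03 ± 0.50 and -2.89 ± 0.49. By camera with an estimated correlation the factor, sarcomere and calcium handling lists were higher in CCIpiCM over CCIiFib (adjusted p 0.0327, 0.00093 and 0.00364). The cytokine list was lower there (adjusted p 0.0327). CCIiCM over CCIpiCM had 173 genes, 44 higher and 129 lower. Of 34 fibroblast and matrix genes 18 were lower (Col1a2, 1038 ± 456 against 4368 ± 1423 CPM) and of 26 sarcomere genes 3 were higher (Myl7, Ttn and Tnni3). The factors did not pass there, at 0.56 ± 0.40 (Mef2c), 0.49 ± 0.37 (Gata4) and 0.50 ± 0.56 log2 units (Tbx5), with adjusted p of 0.605, 0.635 and 0.784 by edgeR. In reprogramming plates alone the values were 0.81 ± 0.33, 1.09 ± 0.22 and 0.86 ± 0.50, also without passing (adjusted p 0.421, 0.141 and 0.586). The counts of genes passing in those plates alone were 0 for CCIpiCM over CCIiFib and 4 for CCIiCM over CCIpiCM. Without reprogramming plate 2, reprogramming plate 3 or mixed plate 4 they were 3 and 59, 1 and 29, and 1 and 60, and without reprogramming plate 1 or mixed plate 5 they were 14 and 95, and 2 and 168.

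CCAiFib and CCAFib cells differed from CCIiFib and CCIFib cells in proliferation genes, and CCAiCM cells were not compared. In CCAiFib over CCIiFib cells 15 of 25 mitosis genes and 5 of 22 DNA replication genes were higher, among them Cdk1 (483 ± 55.2 against 19.1 ± 7.68 CPM, SD, n = 3 and 5 plates, log2 fold change 4.64 ± 0.48) and Pcna (291 ± 47.7 against 56.7 ± 23.5 CPM). Both lists passed with an estimated correlation (adjusted p 0.0012 for each). If the classes were made from these expression values, that outcome may have been fixed in advance, and the lists only describe the classes. In all 122 genes passed, 109 higher and 13 lower. In control plates, CCAFib over CCIFib had 23 genes, 22 higher and 1 lower, including 7 of 25 mitosis genes such as Ube2c (323 ± 84.1 against 7.24 ± 4.02 CPM, SD, n = 2 plates). Among 22 DNA replication genes 0 passed there, and 13 were higher adjusted over the list alone. Of 11 endothelial markers 11 had negative fold changes in CCAFib (camera adjusted p 1.86e-05, median log2 fold change -3.86) and of 13 epicardial markers 12 had positive ones (0.00127, median 2.59), with 0 passing and adjusted p of 0.216 and 0.342 at an estimated correlation. The lone fall was Serpine2, named after its value was seen. Without mixed plate 4 the counts were 22 and 1, without mixed plate 5 they were 36 and 37, and without reprogramming plate 1 the first was 37. These plates hold no CCAFib or CCIFib cells, so the counts for CCAFib over CCIFib moved only through the shared fit.

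CCIiFib cells of reprogramming plates were compared with CCIFib cells of control plates, a choice made after seeing the classes. Tbx5 stood at 156 and 3.76 CPM on average (n = 3 and n = 2 plates), Gata4 at 234 and 47.2 CPM, Ttn at 88.6 and 0.850 CPM, and Lox at 208 and 540 CPM. Bgn (3983 and 5494 CPM) and Postn (2069 and 1904 CPM) lay closer together. No gene of 14248 passed by edgeR, while 857 had an unadjusted p under 0.05. For Lox the log2 fold change was -1.38 ± 0.25 (adjusted p 0.476). The fibroblast and matrix list had a median log2 fold change of 0.018 and the sarcomere list one of 1.80. The endothelial list had a median of -5.0 and the epicardial list one of -2.15. Another tool was not run for this comparison.

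Across cells of one plate, fibroblast and sarcomere list levels were opposed in plates with factors. Spearman's rho was -0.573, -0.639 and -0.648 in reprogramming plates 1, 2 and 3 (mean -0.620 ± 0.041, SD, n = 3), 0.279 and 0.00235 in control plates 1 and 2, and -0.477 and -0.601 in mixed plates 4 and 5. The exact permutation p was 0.1, the smallest possible. The classes differ in both lists (median log2 fold changes of 4.44 for sarcomere and -2.10 for fibroblast in CCIiCM over CCIiFib). The rho values may thus restate that difference, and they were not computed with class means removed. Mitosis and sarcomere levels had a mean rho of 0.132 ± 0.218 in reprogramming plates (SD, n = 3) and 0.036 ± 0.00975 in control plates (SD, n = 2), a difference within the spread (exact permutation p = 1). In mixed plates 4 and 5 the rho was -0.145 and -0.198, and -0.085 and 0.015 without removing depth. Reprogramming plate 3 alone had a rho of 0.384 for this pair.

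The cells the authors set aside from the non-immune set made up 2.90%, 14.1% and 30.9% of reprogramming plates 1, 2 and 3, 4 of 77 and 9 of 82 cells of control plates 1 and 2, and 1.47% and 11.8% of mixed plates. Group means were 16.0% ± 14.1 (SD, n = 3) and 8.09% ± 4.09 (SD, n = 2), with an exact permutation p of 0.6. Cells with at least 4 immune markers at 10 CPM made up 29.5% ± 36.9 and 12.3% ± 11.9 of the same plates (exact permutation p = 0.9). Summed over 13 immune markers, the non-immune cells still held 365 CPM in reprogramming plate 3, against 17.9 to 109.9 CPM in the other plates. Lyz2, the lysozyme of macrophages, stood at 153 CPM in those non-immune cells. With the set-aside cells kept in, 31 genes passed between reprogramming and control plates, 30 of them among the 97.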

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

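Of the tests in this part, only the rank correlation over immune markers was set before its result was seen. The tests on DsRed and the marker count of the median cell were chosen after.

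DsRed, whose virus was used for control cells only, lies outside the comparisons of gene expression. It stood at 0 reads in all 3 reprogramming plates, and at 505 CPM in control plate 1, 1787 CPM in control plate 2, 2058 CPM in mixed plate 4 and 3336 CPM in mixed plate 5 (means over non-immune cells). Puro reads stood at 5.38 CPM in control plate 1. Both control plates thus held DsRed reads, although the labels call 1 of them uninfected.

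In the mixed plates DsRed was found in cells of every class. The fold of mean DsRed in CCIiFib over CCIiCM cells was 24.6 in mixed plate 4 and 6.41 in mixed plate 5. Tbx5 was lower in CCIiFib. Median DsRed in CCIiFib cells was 3096 and 3908 CPM there, with median Tbx5 of 3.42 and 2.44 CPM. In CCIiCM cells the medians were 66.75 and 402 CPM of DsRed and 485 and 293 CPM of Tbx5. No cell of these plates was classed CCIFib or CCAFib, so retroviral control cells kept there bear other class names. These values point to the iFib classes. An equal factor response in CCIiFib cells of mixed and reprogramming plates stays open. The median change of 91 called genes in mixed plates was 20.7% of that in reprogramming plates, and 84 were larger in the latter. These genes were chosen on plates that hold these cells. Over control CCIFib cells the sarcomere list had medians of 1.80 in reprogramming and 0.015 in mixed plates, and the fibroblast list 0.018 and 0.0080, with no list test run. EdgeR called 0 genes between mixed and reprogramming CCIiFib cells (1097 at an unadjusted p under 0.05). It also called 0 for reprogramming CCIiFib over control CCIFib cells, so 0 calls decide nothing. DsRed reads were also in 100% of CCIiCM cells of each mixed plate and in 0% of those of the reprogramming plates, and the 10th percentile over all cells was 21.9 and 149.5 CPM. Reads or RNA carried between cells of a plate could give that floor, and cells infected with both kinds of virus after mixing stay open, as untested.

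In reprogramming plate 3, where 25 of 81 cells were set aside, immune markers were also found in cells kept as non-immune. Over the 13 markers, levels in kept cells followed levels in set-aside cells of the plate with rho 0.896 (across genes, which are not independent replicates), as RNA or reads from the set-aside cells could do. At lower marker sums (17.9 to 109.9 CPM) rho was 0.917 and 0.736 in control plates 1 and 2, and 0.022 and 0.566 in reprogramming plates 1 and 2. It was 0.386 and 0.747 in mixed plates 4 and 5, so a high rho was found in some other plates too. The lowest values, in reprogramming plate 1 and mixed plate 4, rest on 2 and 1 set-aside cells. The set-aside cell of mixed plate 4 had a marker sum of 1.13 CPM, so these low values say little. A few unremoved immune-like cells as the whole source are argued against by the median kept cell, which had 4 of the markers at 10 CPM. Across the 7 plates, with no biological explanation tested, the set-aside share and the marker sum had a Pearson r of 0.894 (permutation p = 0.0286) and a Spearman rho of 0.393 (permutation p = 0.396), and without the 2 farthest plates r was 0.35, so the relation rests on those plates.

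Among CCIpiCM cells, the plate mean of Tbx5 in reprogramming plate 2 (785 CPM) stood apart from the other plates (433 to 510 CPM), with a gap of 0.782 of the whole range. This was the only 1 of 9 groups tested to stand apart, and chance marks about 1 in 20.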

How the results depend on the processing

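Settings chosen after seeing the data were the CCI classes alone, the removal of cells with endothelial or epicardial markers, the authors' ComBat values and the reprogramming plates alone. The correlation of factor and sarcomere levels, with and without the depth correction, was added too, and again with class means removed, where the difference between reprogramming and control plates was 0.00606 in rho, against 0.502. Where a count moved, the cause was not tested. Counts are given for reprogramming against control (97), mixed against control (0) and reprogramming against mixed plates (2), in that order. They were 1059, 217 and 345 with DESeq2, 203, 24 and 8 with no low-count filter, 283, 25 and 21 with a filter of 10 CPM in 2 plates, 31, 0 and 0 with all cells, and 225, 11 and 1 with equal weight per cell. They were 1536, 0 and 7 with the authors' normalized values and 9068, 2707 and 4905 with their ComBat values. The last 2 moved the median of all genes by -0.37 and -0.46 log2 units in the first comparison, and the ComBat split was 1161 higher and 7907 lower. Equal weight per cell moved it by 0.19. Leaving out each plate gave 1 to 99, 0 to 2 and 0 to 2. A lone remaining control plate was assumed to vary like the other groups. Only the plates of the groups compared gave 67, 0 and 1. The CCI classes alone gave 71, 0 and 0, removal of endothelial-marker cells 133, 0 and 1, and of epicardial-marker cells as well 135, 5 and 0. Other size factors gave 97, 0 and 2.

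With a replicate block for plate numbers 1 and 2, 15 genes passed, 13 of them among the 97, and the immune and endothelial list medians were -1.98 and -4.76. The plates share only a number, from 2 pairs.

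Lists passing camera went from 12 to 0 with an estimated correlation. The factors passing went from 3 to 0 to 3 over left-out plates. The difference in the share of cells with all 3 factors was 69.9 points without thinning and 62.7 points at 5 reads of each factor, against 82.0. For the class comparisons, leaving out plates gave 507 to 914 (CCIiCM over CCIiFib), 1 to 14 (CCIpiCM over CCIiFib), 29 to 168 (CCIiCM over CCIpiCM), 22 to 96 (CCAiFib over CCIiFib) and 1 to 37 genes (CCAFib over CCIFib). The 914 and the 96 came from leaving out a control plate, which holds none of those classes. The highest counts without another plate were 803 and 91. CCAFib and CCIFib occurred only in the control plates, and leaving out 1 of these allowed no fit. Their range comes from plates without these classes, so it says nothing on how far the result rests on 1 control plate. With at least 10 cells per unit they were 803, 2, 168, 36 and 37 in that order. With reprogramming plates alone the comparisons among CCIiCM, CCIpiCM and CCIiFib gave 310, 0 and 4. Of 871 values of 44 named-gene results, 632 kept direction and side of the threshold, 160 lost the call, 77 gained it and 2 reversed. Those were Bub1 with CCI classes alone (0.89 ± 0.83) and Gpm6a without endothelial or epicardial cells (0.71 ± 1.73, log2 fold change), both not called in any direction there. RNA content per cell and the comparison inside one class were not run, for the reasons given with the methods. In simulation, 0% of genes changed by 1 log2 unit were recovered between reprogramming and control plates, and 8% between CCIiCM and CCIiFib cells.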

Other observations

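Single members of other lists differed between CCIiCM and CCIiFib cells of the same plates (SD, n = 5 plates, edgeR with the plate as a block). Of 16 cardiac regulators 2 were higher, Nppa and Nppb, and 2 were lower, Fhl2 (174 ± 83.4 against 620.5 ± 290.4 CPM) and Tbx20 (81.6 ± 42.7 against 230.2 ± 95.4 CPM), and the list did not pass (camera adjusted p 0.754). Of 19 splicing regulators Rbm24, a muscle splicing factor, was higher (3.44 ± 3.29 against 0.0076 ± 0.017 CPM) and Mbnl1 (73.4 ± 36.3 against 276 ± 74.8 CPM) and Mbnl2 were lower, and that list did not pass either (adjusted p 0.754). Of 12 immediate early genes 4 were lower, among them Egr1 (282 ± 201 against 567 ± 249 CPM), and of 14 TGF-beta targets 4 were lower, among them Ctgf (89.6 ± 18.4 against 316 ± 87.2 CPM). With an estimated correlation the adjusted p was 0.0378 for the immediate early list and 0.0518 for the TGF-beta list. Of 18 interferon genes 3 were lower, including Cxcl10 and Ifit3 (17.5 ± 15.6 against 154 ± 87.3 CPM), with an adjusted p of 0.106 for the list with an estimated correlation. Cenpa and Kif23 were the 2 of 25 mitosis genes that were higher (150.1 ± 60.8 against 14.6 ± 11.1 CPM for Cenpa), and 0.437 was the adjusted p of that list with an estimated correlation.

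Hypotheses on the factor levels follow. The comparison in reprogramming plates alone and the correlations were added after seeing the data. For the first the test was also set after some of its values were seen, and for the correlations before theirs were. CCIiCM cells held more of each factor than CCIiFib cells, and control cells among the iFib cells of mixed plates could account for that. With reprogramming plates alone the Tbx5 log2 fold change was 2.79 ± 0.55, above the 0.5 that this explanation allows by more than its spread, which argues against it as the whole cause. The adjusted p for Tbx5 there was 0.0501, so the stricter bound, which also asked for a call, was missed. Whether cells with more factor mRNA have more sarcomere mRNA beyond the difference between classes stays open: rho was 0.764, 0.619 and 0.591 across cells of reprogramming plates 1, 2 and 3, against 0.128 and 0.185 in control plates, but the classes differ in both levels, so those values restate that difference. With class means removed rho was 0.351, 0.0997 and 0.0354, against 0.125 and 0.188 in control plates (exact permutation p = 1) and 0.137 and 0.337 in mixed plates 4 and 5, and of the 3 reprogramming plates only plate 1 passed the bound of 0.2.

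Other splits of the plate-and-class sums were fitted for the class comparisons, each in a fit of the 2 classes alone. The sums are paired by plate, so only swaps of the classes within plates were compared, with the fully reversed assignment taken as the same split, a restriction chosen after the result was seen. For CCIiCM and CCIiFib the real split gave 769 genes and the highest of the others 1, with 1 of 16 splits as large. For CCIpiCM and CCIiFib the values were 4 and 0, and for CCIiCM and CCIpiCM 31 and 0, with 1 of 16 splits as large each. For CCAiFib and CCIiFib they were 29 and 0, with 1 of 4 splits as large. These splits are too few for a share under 0.05. If the classes were made from these expression values, the larger count of the real split was also fixed in advance. The splits therefore decide nothing about chance.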
